A study of Homo sapiens with 6 samples.

How the data were processed

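The series holds 6 RNA sequencing libraries of Cal27 spheroids, 3 from soft Matrigel (3 mg/mL) and 3 from stiff Matrigel (12 mg/mL), harvested on day 14. Per the labels' protocols, polyadenylated RNA was selected from 500 ng of total RNA, directional libraries were amplified for 10 cycles, and paired reads of 61 bp were sequenced on a NextSeq 2000 to a mean of 59.7 M reads. Per the submitters' processing notes, FastQC 0.11.7, Trim Galore 0.4.2, cutadapt 1.9.1, STAR 2.6.1e and featureCounts 1.6.2 were used with the hg38 build. The annotation, the strand setting and the treatment of reads with several matches are not given in the sources used here. The deposited counts are whole numbers of fragments per gene symbol for 38167 genes, not normalized, and sum to between 30656278 and 40583044 per library. The deposited TPM values (transcript abundance scaled to a fixed total) are given by the authors to 1 decimal in 1 table per library. For 6173 genes with over 1000 counts in each library, at least 99.27% of the ratios of counts to TPM lay within 5% of a common gene length times a library factor, so the TPM carry the same counts over a fixed length. The kit marks strand, but TALAM1, which lies antisense to MALAT1, had 92.7% to 94.3% of the count of MALAT1 in each library; a gene and a partner that overlaps it on either strand were therefore treated as not told apart. Overlaps were taken from GENCODE release 29, and named genes with at least 10% of their exons covered by 1 partner are given as uncertain, a limit set after the values were seen. No row of the count table lacked a gene name. Gene symbols were matched to a RefSeq table of GRCh38.p14 (36611 of 38167 matched), which gave the Entrez numbers and positions.

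Samples were grouped by their labels, and the only comparison was stiff against soft. The main test, fixed before the data were examined, was edgeR 4.0.16 (quasi-likelihood fit and F test, TMM factors, default expression filter, no covariate) on the deposited counts, run in R 4.3.3, with Benjamini-Hochberg adjustment and a threshold of 0.05; 18676 genes passed the filter. Levels are CPM (counts relative to the TMM-scaled library size) as mean ± SD of 3 libraries. The labels number the replicates 1 to 3 in both conditions without saying that a number marks a shared day, so the number was not used as a block in the main test. For 27 gene lists fixed before the data were examined, the members past the threshold over all genes and those adjusted over the list alone were counted. Each list with at least 5 tested genes (26 lists) was tested with limma 3.58.1's camera on log2 CPM (prior count 2) with a preset correlation of 0.01. Camera called 16 of the 26 lists (12 higher and 4 lower) and 0 with an estimated correlation, where adjusted p was 0.227 or more for each and 3 lists had an unadjusted p under 0.05. The fry test, which asks whether a list's genes move one way on balance, called 20, and its mixed form, which asks whether they change in either direction, called 26; neither compares a list with other genes.

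Genes were named by a rule written beforehand. It took the 10 largest rises and 10 largest falls among named, non-pseudogene genes past the threshold with a mean of at least 5 CPM and no overlap between groups, and up to 4 genes with the smallest p in each list. It added CCN1, CCN2, ANKRD1, AMOTL2, VIM, CDH1, MKI67, ITGB1 and YAP1, and for lists of other cell types the most abundant member. Some genes that the rule takes are not reported here. For SCN2B and VIM, with few fragments in soft, the ratio of summed counts is given with a Clopper-Pearson 95% interval, which covers counting error only because amplified fragments are not independent molecules. Within a condition, log2 CPM correlated across genes at r = 0.988 to 0.994, and between conditions at 0.953 to 0.967. No pair of libraries of the same condition agreed within sampling noise (chi-square per degree of freedom 3.41 to 33.91), and the 2 highest values belonged to the pairs with stiff replicate 2.

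On simulated counts with the real means and library sizes and 200 changed genes of 18413, edgeR recovered 8% of genes changed 1.25-fold, 58% at 1.5-fold, 82% at 2-fold and 96% at 4-fold, with 5.4% of its calls false; DESeq2 1.42.0 had 11.1% of its calls false. Camera called 2 of 2 shifted lists and 0 of 8 others. The simulated genes varied independently, so this check does not cover lists whose genes vary together. Alternatives listed beforehand were DESeq2, other scaling factors, other count filters, a robust dispersion, limma on log2(TPM + 1) and log2(TPM + 0.1) for genes with a mean TPM of at least 1 and without that filter, stricter thresholds, the replicate number as a block and each library left out. Chosen after seeing the data were a correction of each library's trend on gene length, the same with the block, and the counts of list members that rose or fell without stiff replicate 2. The correction fitted a lowess curve (span 0.3) of each library's deviation on the length implied by counts and TPM, left out the ribosomal and mitochondrial lists, and entered as an offset; 95.6% of tested genes had such a length. On simulated data with a length trend it lowered false calls from 5605 to 2 and recovered 70% of 50 genes changed 2-fold.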

Results

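Cal27 is an established human line derived from a squamous cell carcinoma of the tongue. Its cells were grown as spheroids in Matrigel, a basement membrane extract that sets as a gel, at 3 mg/mL (soft) or at 12 mg/mL (stiff) by the liquid overlay technique. RNA was collected on day 14 and polyadenylated transcripts were sequenced. Each condition had 3 libraries, which the labels call biological replicates; nothing in the labels says whether they came from separate cultures or days, so the p-values measure the spread between these libraries. The count table held 38167 genes. The libraries held 40583044, 33470916 and 30656278 counted fragments in soft and 35292340, 36526394 and 36594685 in stiff. The comparison addresses how the stiffness of the surrounding matrix alters the expression profile of oral squamous carcinoma spheroids. Matrigel concentration sets stiffness and the amount of matrix ligand together, so the design holds no separate value for either.

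Camera called 16 of 26 gene lists with a preset correlation and 0 with an estimated correlation (adjusted p of 0.227 or more). The lists called higher in stiff Matrigel than in soft Matrigel included squamous and basal keratinocyte, matrix, cholesterol synthesis, glycolysis, hypoxia and cell cycle genes. Those called lower included interferon response, inflammatory, and unfolded protein and amino acid stress genes. Among genes with a mean of at least 5 CPM, the largest rises included those of KRT1, a keratin of suprabasal keratinocytes (22.3-fold), KRT16, a keratin of activated keratinocytes (13.6-fold), SPRR1A, a precursor of the cornified envelope (10.7-fold), and the carbonic anhydrase CA12 (10.6-fold). The largest falls included those of the retinol-metabolising enzyme DHRS9 (32.3-fold), the polymeric immunoglobulin receptor PIGR (23.7-fold), the tryptophan-degrading enzyme IDO1 (23.7-fold) and the membrane mucin MUC4 (12.7-fold). In edgeR's quasi-likelihood test, 4722 of 18676 tested genes were higher in stiff and 4449 were lower at an adjusted p below 0.05, or 49.1% of the genes tested. Of these, 1419 higher and 1050 lower genes differed at least 2-fold. In 11183 genes (59.9%) the 3 soft and 3 stiff values did not overlap, where chance gives 10%. The first principal component held 75.1% of the variance and separated the conditions. The second held 10.8% and set stiff replicate 2 (-35) apart from stiff replicates 1 (21.5) and 3 (18.3). Higher genes made up 51.5% of the calls. With scaling by library size only, 4181 genes were higher and 5170 lower (44.7% higher), and with limma on log2(TPM + 1) 2880 were higher and 4088 lower (41.3% higher).

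Among genes with a mean of at least 5 CPM, the largest rise by fold belonged to SCN2B (Entrez 6327, chromosome 11, 118162806 to 118176639), which encodes an auxiliary subunit of voltage-gated sodium channels. It had 4 fragments over the 3 soft libraries and 1504 over the 3 stiff libraries, a ratio of 378 with a 95% Clopper-Pearson interval of 147 to 1390 that covers counting error only (adjusted p = 3.51e-08). Its level in stiff was 14.2 ± 0.638 CPM (SD, n = 3). The neighbouring gene SCN4B (Entrez 6330, chromosome 11, 118133377 to 118152823), another subunit of the same channels, rose 42.4-fold, from 0.429 ± 0.272 to 17.7 ± 3.55 CPM (SD, n = 3, adjusted p = 6.08e-07). The other genes with the largest rises above that level were FGFBP1, a carrier of fibroblast growth factors (9.96-fold), EMP3 (9.37-fold), the lipoxygenase ALOX15B (9.32-fold) and the adaptor PAG1 (9.21-fold). Those with the largest falls also included the ubiquitin ligase TRIM31 (24.4-fold), the cadherin CDH5 (18.7-fold), the mucus protein FCGBP (18-fold), the retinol uptake receptor STRA6 (17.4-fold), the chaperone CLGN (13.9-fold) and the glutathione-degrading enzyme CHAC1 (13.3-fold). The lowest adjusted p was 1.84e-08, reached by KRT16, IDO1 and STRA6 among others. Positions are those of the GRCh38 annotation.

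Of 33 tested squamous differentiation genes, 19 rose, 3 fell and 11 did not pass; adjusted over the list alone, 19 rose and 4 fell. KRT16 (Entrez 3868, chromosome 17, 41609778 to 41612767) went from 118 ± 8.11 to 1610 ± 198 CPM (SD, n = 3, adjusted p = 1.84e-08). KRT6A, its usual partner keratin, rose 3.86-fold to 1740 ± 77.4 CPM and ECM1 rose 6.68-fold to 17.6 ± 0.0477 CPM. Of 15 basal keratinocyte genes, 9 rose, 1 fell and 5 did not pass; adjusted over the list alone, 11 rose and 1 fell. The basal keratins KRT5 and KRT14, which together build the filaments of the basal layer, went from 1970 ± 122 to 6490 ± 312 CPM and from 822 ± 90.2 to 5160 ± 392 CPM (SD, n = 3). Both lists were called higher by camera with a preset correlation (adjusted p = 1.35e-05 and 0.000213), but not with an estimated correlation (adjusted p = 0.306 for each). The genes that fell, named after their values were seen, were KRT80, S100A7 and S100A9 of the squamous list and KRT15 of the basal list (2720 to 1650 CPM). Squamous genes that did not pass, also named afterwards, included IVL, KRT4 and KRT13 (adjusted p = 0.058 to 0.93). Some that rose were low in stiff, among them SPRR2A, SPRR2D and SPRR2E (1.99 to 2.51 CPM). Without stiff replicate 2, 5 squamous genes fell rather than 3. Keratins of this family are near-identical in parts, so reads shared between them leave the split among family members uncertain.

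**Figure D1:**
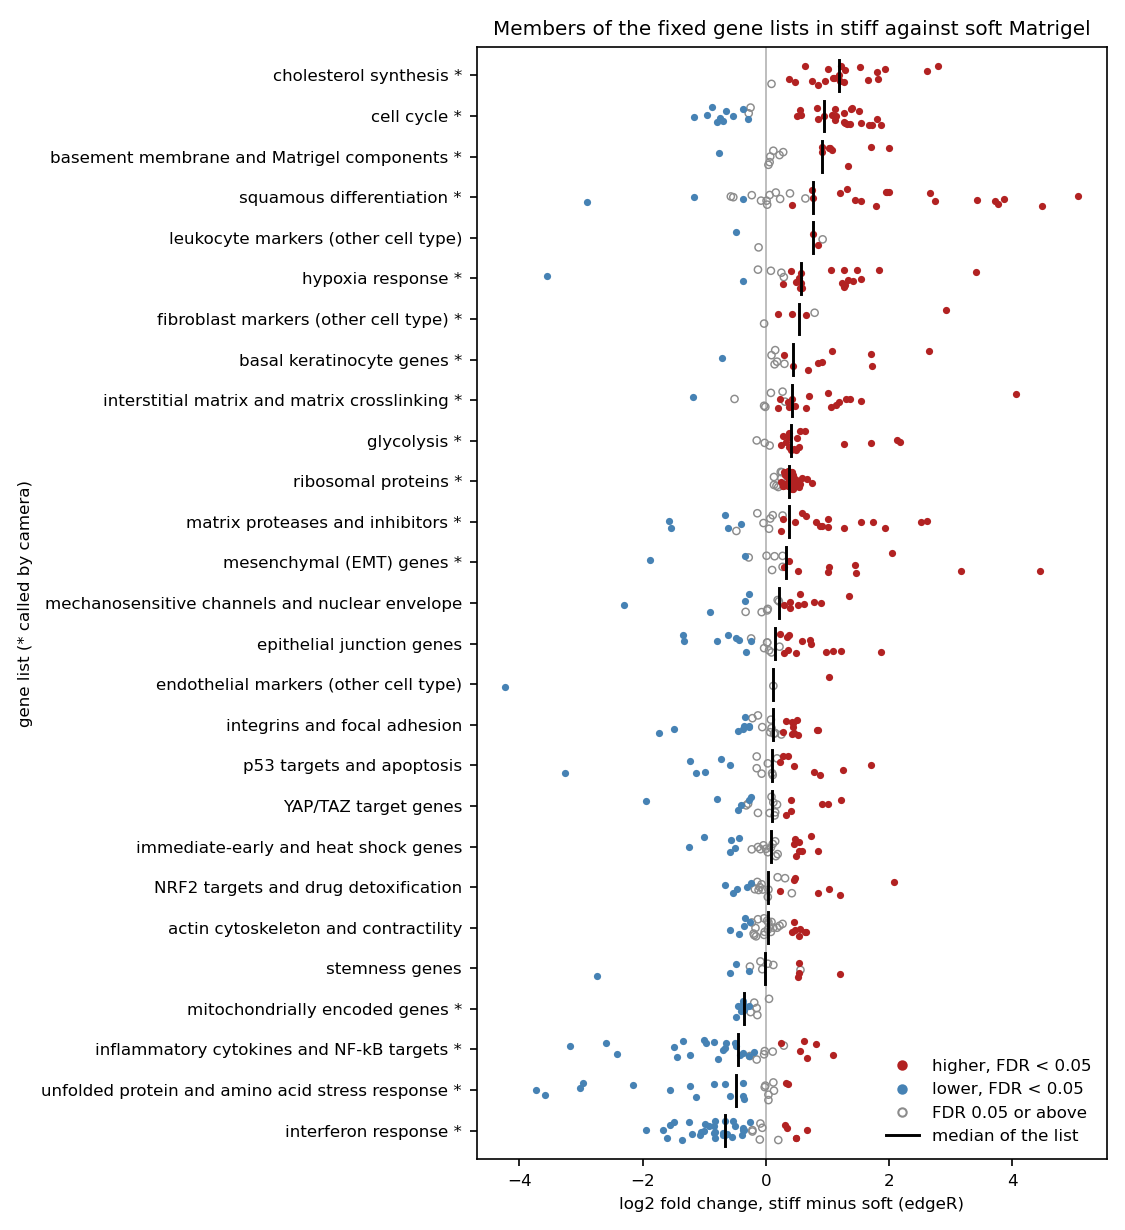
Each point is 1 tested gene of the 27 gene lists, placed by its log2 fold change (stiff minus soft, edgeR, 3 libraries per condition). Red and blue points passed an adjusted p of 0.05, open points did not, the black bar is the median of the list, an asterisk marks the 16 lists called by camera with a preset correlation, and cholesterol synthesis has the highest median (1.18) and the interferon response the lowest (-0.66).

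Of 15 tested basement membrane genes, 8 rose, 1 fell and 6 did not pass, with a median log2 fold change of 0.91; without stiff replicate 2, 13 of 16 rose. COL7A1, the anchoring fibril collagen, rose 4-fold, from 137 ± 12.4 to 547 ± 26.5 CPM (SD, n = 3, adjusted p = 1.82e-07). LAMB3, a laminin chain, rose 1.88-fold, and COL4A2 of type IV collagen rose 2.51-fold. The member that fell was the proteoglycan HSPG2, from 1110 to 650 CPM (named after its values were seen). Of 23 interstitial matrix and crosslinking genes, 16 rose and 1 fell, among them COL6A2 (2.58-fold), COL6A1 (2.28-fold), THBS1 (2.21-fold) and the collagen prolyl hydroxylase subunit P4HA1 (2.09-fold). LOXL4, a crosslinking enzyme named after its values were seen, went from 440 to 193 CPM. Of 28 proteases and inhibitors, 16 rose and 5 fell. The urokinase gene PLAU rose 2.02-fold from 737 ± 30.7 to 1490 ± 65.7 CPM, SERPINB5 rose 2.39-fold and MMP28 rose 2.02-fold, whereas the tissue-type plasminogen activator PLAT fell 2.91-fold. The others that fell, named after their values were seen, were MMP12, TIMP3, ADAM10 and KLK6. The 3 lists gave the same counts when adjusted over the list alone. Camera called them higher (adjusted p = 0.000646, 7.44e-05 and 0.00451). With an estimated correlation the calls were lost (adjusted p = 0.53, 0.397 and 0.397). The gene C10orf55 covers 31.1% of PLAU's exons on the opposite strand, so PLAU's counts are uncertain. Fibroblast markers moved with these lists: 4 of 6 rose and 0 fell (camera adjusted p = 0.0374, and adjusted p = 0.397 with an estimated correlation).

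YAP and TAZ are transcriptional co-activators whose target genes are commonly read as a response to stiffness. Of 21 tested target genes, 6 rose, 6 fell and 9 did not pass, with the same counts rising and falling when adjusted over the list alone, and camera did not call the list (median log2 fold change 0.09, adjusted p = 0.757). The matricellular gene CCN2 (Entrez 1490, chromosome 6, 131948176 to 131951372) fell 3.86-fold, from 19.9 ± 6.08 to 5.15 ± 0.732 CPM (SD, n = 3, adjusted p = 5.95e-05), and AMOTL2 fell 1.73-fold. F3, the initiator of coagulation, rose 2.33-fold to 655 ± 22.9 CPM and the kinase NUAK2 rose 1.88-fold. CCN1 was at 37.8 ± 8.03 CPM in soft and 41.7 ± 3.71 CPM in stiff (adjusted p = 0.413), and ANKRD1, at 0 to 6 fragments per library, lay below the count filter. YAP1 itself was 1.23-fold higher (adjusted p = 0.00793), a call lost with limma on log2(TPM + 1) (adjusted p = 0.238, between 2.12e-05 and 0.314 over all alternatives). The count of targets that fell was 3 without soft replicate 1 and also 3 without soft replicate 3.

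Camera called none of the integrin, actin and mechanosensor lists, each of which held genes that rose and genes that fell. Of 28 integrin and focal adhesion genes, 11 rose and 8 fell (12 and 8 adjusted over the list alone; camera adjusted p = 0.337). CAV1 and ITGA5 rose 1.79-fold and 1.77-fold, ITGA1 and TLN2 fell 2.8-fold and 3.32-fold, and ITGB1 was at 202 ± 11 and 194 ± 21 CPM (SD, n = 3, adjusted p = 0.605). The call of TLN2 was lost with limma on log2(TPM + 1) without a filter (adjusted p = 0.215, between 1.18e-09 and 0.215 over all alternatives). Of 31 actin and contractility genes, 7 rose and 5 fell (camera adjusted p = 0.757), including RHOC (1.47-fold higher), CNN3 (1.45-fold higher), TAGLN2 (1.39-fold higher) and TPM1 (1.5-fold lower). The others that fell, named after their values were seen, were SRF, ACTG1, CALD1 and ROCK1. Without stiff replicate 2, 16 integrin and focal adhesion genes rose and 8 fell, still without a call (camera adjusted p = 0.0627). In the same setting 11 actin genes rose and 8 fell. With scaling by library size only the actin list's median turned from 0.03 to -0.03. Of 19 mechanosensitive channel and nuclear envelope genes, 9 rose and 4 fell, such as LMNB1 (1.86-fold higher), TMEM63B (1.72-fold higher), SUN2 (1.47-fold higher) and SYNE1 (4.96-fold lower). TMEM63A, NUP93 and TRPM7, named after their values were seen, also fell. Camera did not call this list (adjusted p = 0.148), but called it higher without stiff replicate 2 (adjusted p = 0.036, between 0.036 and 0.226 with each library left out). Over all 6 libraries the adjusted p was 0.452 with an estimated correlation, and fry called the list higher (adjusted p = 0.0145). The actin and mechanosensor counts were the same when adjusted over the list alone.

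Of 18 tested mesenchymal genes, 10 rose, 2 fell and 6 did not pass (11 and 2 adjusted over the list alone). The activin subunit INHBA rose 4.14-fold to 460 ± 50.2 CPM, the galectin LGALS1 rose 8.92-fold to 127 ± 19.7 CPM, PDPN rose 2.75-fold and the growth factor TGFB1 rose 2.73-fold. VIM, the intermediate filament of mesenchymal cells, had 12 fragments over the soft libraries and 268 over the stiff libraries, a ratio of 22.4 (95% Clopper-Pearson interval 12.6 to 44, counting error only), and reached 2.52 ± 0.151 CPM (SD, n = 3). Of the members named after their values were seen, WNT5A and TGFBR2 fell, and TWIST1, FN1, ZEB1, ZEB2, CDH2 and SNAI1 did not pass (adjusted p = 0.0553 to 0.99). Of 6 fibroblast markers, 4 rose with this list, among them LUM (7.55-fold) and ACTA2 (1.57-fold). Camera called the mesenchymal list higher (adjusted p = 0.00216), but not with an estimated correlation (adjusted p = 0.306). Of 28 junction genes, 13 rose and 8 fell, with the same counts adjusted over the list alone and no call by camera (adjusted p = 0.252). GJB6, a gap junction connexin, and PKP1, a desmosomal plaque protein, rose 3.67-fold and 2.32-fold. The tight junction genes TJP3 and CLDN7 fell 2.55-fold and 2.51-fold, and CDH1, which encodes E-cadherin, fell 1.36-fold, from 320 ± 15.7 to 235 ± 25 CPM (SD, n = 3, adjusted p = 0.00194).

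Of 23 tested cholesterol synthesis genes, 22 rose, 0 fell and 1 did not pass, with the same counts adjusted over the list alone and a median log2 fold change of 1.18. INSIG1, a sterol-regulated brake on the pathway, rose 6.93-fold, from 42.2 ± 1.31 to 292 ± 24 CPM (SD, n = 3, adjusted p = 1.84e-08), MSMO1 rose 6.09-fold and HMGCS1 rose 3.82-fold. Of 21 glycolysis genes, 18 rose and 0 fell, also when adjusted over the list alone, among them ALDOC (4.37-fold), ENO2 (3.25-fold), the glucose transporter SLC2A1 (2.4-fold) and GPI (1.55-fold). Without stiff replicate 2, 1 glycolysis gene fell. Of 25 hypoxia-responsive genes, 19 rose and 2 fell (21 and 2 adjusted over the list alone), including CA12 and NDRG1 (2.77-fold, to 2530 ± 166 CPM). STC2, a secreted glycoprotein that also belongs to stress responses, fell 11.7-fold, from 119 ± 13.2 to 10.1 ± 1.34 CPM, and VLDLR, named after its values were seen, from 44.3 to 34 CPM. VEGFA, named after its values were seen, was at 500 CPM in soft and 456 CPM in stiff (adjusted p = 0.175). Camera called the 3 lists higher (adjusted p = 3.43e-15, 1.73e-06 and 7.13e-07). With an estimated correlation the calls were lost (adjusted p = 0.227, 0.306 and 0.306).

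Of 35 cell cycle genes, 23 rose, 10 fell and 2 did not pass (23 and 11 adjusted over the list alone). TOP2A, the topoisomerase of condensing chromosomes, rose 2.62-fold, from 110 ± 3.24 to 288 ± 5.4 CPM (SD, n = 3, adjusted p = 2.56e-07), CDC20 rose 2.85-fold, BUB1 rose 2.61-fold and PLK1 rose 2.44-fold. The genes that fell, named after their values were seen, included MCM2, MCM3, MCM4, MCM5, MCM6 and MCM7, subunits of the replicative helicase, the origin licensing factor CDC6, E2F1 and CCND1. MCM2 went from 42.6 to 22 CPM and CCND1 from 263 to 156 CPM. MKI67 was at 84.5 ± 9.21 CPM in soft and 151 ± 42.5 CPM in stiff (adjusted p = 0.00353), with 102 CPM in stiff replicate 2 against 173 and 178 CPM in the other stiff libraries. The MKI67 call was lost with limma on log2(TPM + 1) (adjusted p = 0.0845, between 6.07e-13 and 0.153 over all alternatives). Camera called the list higher (adjusted p = 0.000301), but not with an estimated correlation (adjusted p = 0.306).

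**Figure D2:**
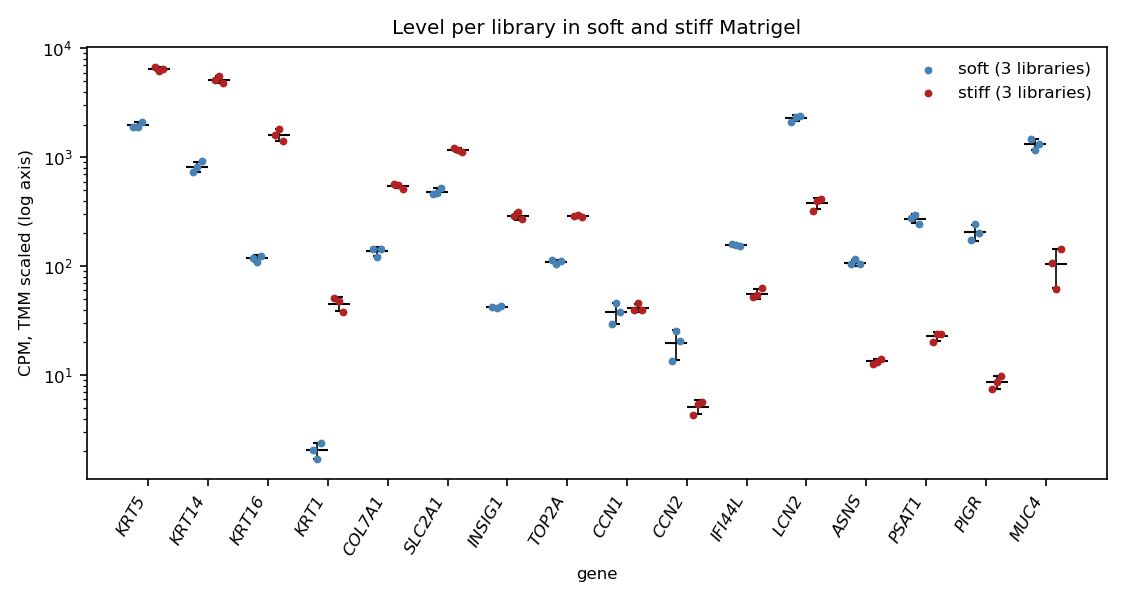
CPM after TMM scaling (log axis) of 16 named genes in the 3 soft (blue) and 3 stiff (red) libraries, with the mean (black dash) and the SD (bars). The groups of CCN1 overlap (37.8 and 41.7 CPM on average), the keratins are higher in every stiff library, and CCN2, IFI44L, LCN2, ASNS, PSAT1, PIGR and MUC4 are lower.

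Of 42 tested interferon response genes, 31 fell, 5 rose and 6 did not pass (31 and 6 adjusted over the list alone), and 3 rose without soft replicate 1. XAF1 fell 3.83-fold, MX2 fell 3.03-fold, IFI44L fell 2.81-fold from 158 ± 3.18 to 56.2 ± 5.7 CPM (SD, n = 3, adjusted p = 6.67e-07), and the RNA sensor IFIH1 fell 2.38-fold. The genes that rose, named after their values were seen, included HLA-E, RSAD2, HERC5 and OASL. Of 32 inflammatory and NF-kB target genes, 20 fell, 6 rose and 6 did not pass, also when adjusted over the list alone. The iron-binding defence protein LCN2 fell 6.05-fold, from 2290 ± 142 to 379 ± 46.6 CPM (SD, n = 3, adjusted p = 1.01e-07), the chemokine CCL20 fell 5.33-fold, TNFAIP2 fell 2.83-fold and BIRC3 fell 2.36-fold. Camera called both lists lower (adjusted p = 8.42e-09 and 0.000301). With an estimated correlation the calls were lost (adjusted p = 0.306 and 0.397). The gene PRAL covers 38.3% of XAF1's exons on the opposite strand, so XAF1's counts are uncertain.

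Of 22 tested unfolded protein and amino acid stress genes, 14 fell, 2 rose and 6 did not pass, also when adjusted over the list alone. PSAT1, an enzyme of serine synthesis, fell 12-fold, from 274 ± 25.9 to 22.7 ± 2.09 CPM (SD, n = 3, adjusted p = 1.84e-08). CHAC1 fell 13.3-fold, asparagine synthetase ASNS fell 8.07-fold and the cystine transporter SLC7A11 fell 7.85-fold. Among the chaperones of the list, named after their values were seen, HSPA5 went from 1010 to 636 CPM (adjusted p = 3.15e-05), CALR rose from 684 to 873 CPM (adjusted p = 0.00184) and HSP90B1 was at 831 and 905 CPM (adjusted p = 0.119). The other gene that rose was MANF, from 24.7 to 30.9 CPM. Without soft replicate 1, soft replicate 2 or soft replicate 3, 1 gene of the list rose rather than 2, as with scaling by library size only. Camera called the list lower (adjusted p = 2.71e-05), but not with an estimated correlation (adjusted p = 0.306). An annotated transcript on the same strand covers 44.6% of the exons of ASNS, so its counts are uncertain.

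Of 39 ribosomal protein genes, 32 rose and 0 fell (35 and 0 adjusted over the list alone), with a median log2 fold change of 0.38. RPS27, RPL7A, RPS15 and RPL11 rose 1.68-fold, 1.58-fold, 1.5-fold and 1.47-fold. Short genes in general were higher in stiff. Across 10 groups of genes of equal size ordered by gene length, the median log2 fold change went from 0.137 in the shortest genes to -0.126 in the longest, and stiff replicate 2 deviated from the other stiff libraries by 0.25 in the shortest and by -0.222 in the longest. Without stiff replicate 2 the medians of the shortest and longest groups were 0.056 and -0.068, and that of the ribosomal protein genes was 0.28. Of 13 mitochondrially encoded genes, 0 rose and 8 fell (10 adjusted over the list alone), among them ATP6 (1.39-fold lower), ATP8 (1.37-fold lower), CYTB (1.33-fold lower) and ND1 (1.29-fold lower). These 13 genes took between 3.79% and 4.2% of the fragments in soft and between 3.04% and 3.23% in stiff. Camera called the ribosomal list higher (adjusted p = 2.83e-07) and the mitochondrial list lower (adjusted p = 0.00271). With an estimated correlation the calls were lost (adjusted p = 0.53 and 0.457). Ribosomal protein genes share sequence with many pseudogenes, so their counts are uncertain.

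Among stemness genes, 4 of 14 rose and 4 fell, also when adjusted over the list alone (camera adjusted p = 0.757). CD44, a hyaluronan receptor, rose 2.3-fold to 2290 ± 283 CPM, SOX9 rose 1.45-fold, EZH2 rose 1.44-fold and ALDH1A3, of which an opposite-strand gene covers 27.5%, fell 1.5-fold. The others that changed, named after their values were seen, were SOX2 (higher) and NOTCH1, KIT and MYC (lower). The list's median (-0.01) and mean (-0.07) lay below 0 while camera's direction was upward, and the median turned positive without soft replicate 3 or without any 1 of the stiff libraries. Of 23 NRF2 target and detoxification genes, 7 rose and 5 fell (8 and 6 adjusted over the list alone; camera adjusted p = 0.55), including AKR1B10 (4.23-fold higher), ALDH3A1 (2.3-fold higher), OSGIN1 (2.03-fold higher) and AKR1C3 (1.8-fold higher, of a family with near-identical members). Those that fell, named after their values were seen, were TXNRD1, ABCC1, ABCC4, AKR1C2 and SRXN1, of which a same-strand transcript covers 85%. The number of these that fell was 3 without soft replicate 1, soft replicate 2, stiff replicate 1 or stiff replicate 3. Their median of 0.03 turned to -0.02 with scaling by library size only, to -0.05 without soft replicate 1, to -0.02 without stiff replicate 1 and to -0.01 without stiff replicate 2. Of 25 immediate-early and heat shock genes, 8 rose and 6 fell, also when adjusted over the list alone (camera adjusted p = 0.756). The chaperones HSPA8 and HSPH1 fell 2.38-fold and 2-fold while HSPB1 and BAG3 rose 1.79-fold and 1.45-fold. For this list fry's direction was downward and camera's upward. Of 21 p53 target and apoptosis genes, 8 rose and 6 fell (9 and 6 adjusted over the list alone; camera adjusted p = 0.756), and 5 rose without soft replicate 1 or without soft replicate 2. The cell cycle inhibitors BTG2 and CDKN1A rose 3.28-fold and 2.38-fold, and the stress cytokine GDF15 fell 9.57-fold from 76.7 ± 9.87 to 8.01 ± 2.23 CPM (SD, n = 3). This list's median (0.1) and mean (-0.09) differed in sign.

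Of the markers of other cell types, 6 of 12 fibroblast, 3 of 10 endothelial and 5 of 13 leukocyte genes had enough counts to be tested. Of 6 tested fibroblast markers, 4 rose and 0 fell, also when adjusted over the list alone. The proteoglycan LUM rose 7.55-fold to 17.3 ± 1.07 CPM, ACTA2 rose 1.57-fold to 7.95 ± 0.304 CPM and FBLN1, the most abundant, rose 1.34-fold to 94.2 ± 1.41 CPM. COL1A1 was 1.15-fold higher at 82.6 ± 3.41 CPM (adjusted p = 0.0432), a call that was lost when any library but stiff replicate 2 was left out (adjusted p = 0.0025 without stiff replicate 2 and up to 0.189 without another), with scaling by library size only, without a count filter and with limma on TPM. Camera called this list higher (adjusted p = 0.0374), but not with an estimated correlation (adjusted p = 0.397), nor without stiff replicate 1 (adjusted p = 0.0554) or stiff replicate 3 (adjusted p = 0.0557), between 0.0131 and 0.0557 with each library left out. Of 3 tested endothelial markers, CDH5 fell from 10.4 ± 1.41 to 0.552 ± 0.267 CPM, VWF rose 2.03-fold to 3.22 ± 0.577 CPM and PECAM1 was at 0.292 ± 0.112 and 0.31 ± 0.0956 CPM (SD, n = 3, adjusted p = 0.834). Of 5 tested leukocyte markers, 2 rose and 1 fell, also when adjusted over the list alone (camera adjusted p = 0.462). CD68 rose 1.8-fold to 101 ± 3.2 CPM, ITGAM rose 1.7-fold to 4.99 ± 0.57 CPM, CD14 fell 1.4-fold to 36.6 ± 4.58 CPM, and CD4 was at 0.243 ± 0.0903 and 0.453 ± 0.214 CPM (adjusted p = 0.142). The calls of VWF and ITGAM were lost with limma on log2(TPM + 1) without a filter, where their adjusted p was highest over all alternatives (adjusted p = 0.0554 for each). A transcript on the same strand covers 81.7% of the exons of CD68, so its counts are uncertain. So, with 10% to 22.7% of their exons covered by 1 partner, are those of MCM2, ATP8, KLK6, ACTA2, TPM1, HMGCS1, OSGIN1, EMP3, VIM, HSPG2, PLK1, CLDN7, RHOC, SUN2, CCND1, ALDOC and YAP1.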

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

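The length correction, alone or with the block, and the counts of list members that rose or fell without stiff replicate 2 were chosen after seeing the data; the other settings were fixed before. The counts of genes higher (4722) and lower (4449) in stiff stayed within 1.5 times under DESeq2, other scaling factors, other count filters, a robust dispersion, a threshold of 0.01 and the length correction (4924 and 4686). Leaving out each library in turn gave 3746 to 5379 higher and 3410 to 5224 lower genes, the most without stiff replicate 2. Fewer genes were higher with limma on log2(TPM + 1) (2880), on log2(TPM + 0.1) (2831) and on log2(TPM + 1) without a filter (3138). These settings kept 67%, 65.6% and 68.7% of the main calls. The median log2 fold change of all their genes was -0.094, -0.111 and -0.038, against -0.057 with scaling by library size only. The cause was not tested. A minimum change of 2-fold left 1419 higher and 1050 lower genes by construction. The 16 lists called by camera became 0 with an estimated correlation (3 at an unadjusted p under 0.05; fry called 20 and its mixed form 26) and 15 to 17 with a library left out. With the replicate number as a block, 5167 genes were higher and 5039 lower and 16 lists were called, and with the block and the length correction 5259 and 5195 genes; the block changed no call of the 124 named genes or the 26 lists, and 5 rather than 3 squamous genes fell. Deviations of same-numbered libraries correlated across genes at r = 0.073, 0.216 and 0.05, and not every library correlated best with its own number.

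Of the 124 named genes tested, COL1A1, MKI67, YAP1, TLN2, VWF and ITGAM lost their call in at least 1 of up to 18 settings, with adjusted p up to 0.522, 0.153, 0.314, 0.215, 0.0554 and 0.0554. The sign turned for 3 genes and 3 lists that were not called in the main test, and the cause was not tested. With a library left out, PECAM1 ranged from -0.19 to 0.36, CCN1 from -0.01 to 0.3 and ITGB1 from -0.11 to 0.03 on the log2 scale, and the medians of the stemness list from -0.06 to 0.12 and of the NRF2 list from -0.05 to 0.1. With scaling by library size only, the medians of the actin and NRF2 lists were -0.03 and -0.02. That scaling moved the median of all genes by -0.057. In the simulation, where 200 of 18413 genes changed, the test recovered 8% of the smallest changes. In the real data 49.1% of tested genes were called, so the share recovered there can differ and was not measured. A gene without a call can still differ by as much as the smallest simulated change, or by more. In the simulation edgeR recovered 58% of genes changed 1.5-fold, 82% at 2-fold and 96% at 4-fold.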

Other observations

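The 7 gene lists used here, the tests of carry-over, of fibroblasts and of stiff replicate 2, and the test of length as the whole cause of the ribosomal pattern were chosen after the results of the report were seen, and the bounds of these 4 tests were set once their values were known. Genes of glandular and secretory epithelium were mostly lower in stiff: of 26 tested, 19 fell and 5 rose (median log2 fold change -1.34, camera adjusted p = 1.29e-06, and adjusted p = 0.0458 with an estimated correlation). This list was drawn up after some of its members had been seen to fall, so its p is not independent evidence. Camera's p-values for the 7 lists were adjusted over these 7 only, not over the 26 lists tested before. Besides PIGR, FCGBP and MUC4, which were among the genes already seen to fall, KRT7, a keratin of simple epithelia, fell 9.22-fold from 16.3 ± 2.11 to 1.76 ± 0.613 CPM, GABRP fell 6.9-fold, the secretory cell factor SPDEF fell 4.21-fold and MUC16 fell 3.15-fold from 233 ± 35.7 to 74 ± 25.4 CPM (SD, n = 3). KRT19 went the other way (2.03-fold higher), and KRT8 was 1.17-fold higher. Complement and acute phase genes split: of 15 tested, 8 fell and 6 rose (camera adjusted p = 0.322). C3 fell 3.13-fold from 3240 ± 151 to 1040 ± 198 CPM, and CP, of which an opposite-strand gene covers 19.4%, fell 3.84-fold, while the classical pathway genes C1R (11.4% covered by a same-strand gene) and C1S rose 1.58-fold and 1.6-fold and the complement regulators CD59 and CD55 rose 1.79-fold and 1.69-fold.

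SCN2B and SCN4B lie 9982 bp apart on chromosome 11. Coding genes next to the pair moved far less: on one side TMPRSS4 changed by -0.22 on the log2 scale (adjusted p = 0.0127), and on the other MPZL3 and MPZL2 changed by 0.34 and 0.38 (adjusted p = 0.0168 and 0.000945), against 5.41 for SCN4B. The transcript LOC105369517 on the first side, at a mean of 2.2 CPM, changed by -1.07 (adjusted p = 0.00992). Over all 6 libraries, 1 of the 10 splits into 3 and 3, the real one, gave as many called genes (9171); the highest of the other splits gave 0 (edgeR; at most 433 genes at an unadjusted p under 0.05, against 10366). With 10 splits the share cannot fall under 0.05.

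The fall of amino acid stress genes was weighed first, and a length trend between libraries is argued against. Over all 22 tested genes of the list the median log2 fold change was -0.48 before and -0.47 with the trend removed. The trend itself was small, with medians from 0.137 in the shortest genes to -0.126 in the longest. The 14 fallen members had a median of -1.23 with the trend removed, against -1.18 before. They were picked for having fallen, so this median adds little. A candidate explanation is a fall, as a whole, of the programme driven by ATF4, the transcription factor of amino acid deprivation. Of 31 programme genes outside the first list, 26 fell and 3 rose, with a median of -0.95. Camera's adjusted p with an estimated correlation was 0.0458, over the 7 lists used here rather than the 26 tested before. The list was chosen after genes of the first list had been seen to fall, so its p is not independent evidence. WARS1 fell 5.08-fold, GPT2 fell 6.49-fold and AARS1 fell 3.19-fold, whereas the amino acid transporter SLC38A2 rose 1.63-fold. A parallel fall of the endoplasmic reticulum chaperone programme stays open, since of 16 such genes 7 fell and 0 rose (10 and 0 without stiff replicate 2), the median was -0.12, or -0.22 with the trend removed, and camera called the list (adjusted p = 0.0105) but not with an estimated correlation (adjusted p = 0.184). Why the programme would differ between the gels was not tested; the design leaves the gel's stiffness, its ligand content and nutrient supply through it in place together.

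The rise of basement membrane genes was weighed next. Whether RNA was carried over from Matrigel cannot be decided here, since reads were counted against the human genome alone, which does not measure RNA of another species. In these human counts the laminin chains in which Matrigel is rich did not move with the list. LAMB1 and LAMC1 had a mean log2 fold change of 0.16 against the list's median of 0.91. LAMA1 stayed at or below 0.209 CPM in every library (here and for NID1, COL3A1 and DCN relative to the library total without TMM scaling). NID1, also a Matrigel component, was higher in each stiff library (0.368, 0.274 and 0.547 CPM against 0.148, 0.12 and 0.13 CPM in soft). Fibroblasts among the cells are argued against as the source of the rise, since COL1A2 changed by -0.03 and COL3A1 and DCN reached at most 0.0548 and 0.34 CPM in a stiff library, although LUM, FBLN1, ACTA2 and COL1A1 rose, camera called the fibroblast list (adjusted p = 0.0374, but adjusted p = 0.397 with an estimated correlation, and 0.0554 and 0.0557 without stiff replicate 1 or 3) and DCN was higher in each stiff library (0.34, 0.11 and 0.137 CPM against 0.0493, 0 and 0 CPM). A length trend is argued against, since removing it moved the list's median up, from 0.91 to 0.95. Long genes were lower in stiff in general, so removal could hardly have lowered a list with long genes such as COL7A1 and COL4A2. That result therefore lends no weight to another cause. One hypothesis, found and tested on the same data, is that the carcinoma cells themselves may express more anchoring matrix in the stiff gel. RNA carried over from the gel stays open beside it.

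The rise of ribosomal protein genes was weighed last. With the length trend removed, their median log2 fold change was 0.27 rather than 0.38. That value lies between the bounds set beforehand for and against the trend, so the planned test could not decide. A part of the rise may come from the trend, and that part cannot be told apart from the rest because the correction rests on other genes. In a test added afterwards, 32 of the 39 genes were still called higher, which argues against the trend as the whole cause. However, these genes varied between libraries almost as 1 measurement (an estimated correlation among them of 0.951, and camera adjusted p = 0.53 with it before the correction). Stiff replicate 2 alone is argued against, since without it the median was 0.28 and 33 genes were called higher. RNA integrity, which could set such a trend, has no value in the labels.

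Hypotheses on the cell cycle and on lipids were each given a test. If the spheroids in stiff gel held a larger share of cells in G2 or mitosis and a smaller share in S phase, published phase lists would move apart, and they may do so for that reason: the S phase genes had a median log2 fold change of -0.29 (23 of 43 fell, 7 rose) and the G2/M genes one of 1.07 (48 of 54 rose). Of these lists, 10 and 15 genes were also in the fixed lists; over the remaining 33 and 39 the medians were -0.24 and 0.84. The S phase genes that rose included RRM2 (1.78-fold) and E2F8 (2.24-fold), so that list did not move as 1. With an estimated correlation camera called the G2/M list (adjusted p = 0.0119) but not the S phase list (adjusted p = 0.248). Levels in bulk RNA do not separate more cells in a phase from more transcript per cell. Fatty acid synthesis genes moved in the way that a rise of lipid synthesis beyond cholesterol would give. Of 17 tested, 11 rose and 0 fell (median 0.47), led by SCD (2.53-fold) and FASN (2.65-fold). Without stiff replicate 2, 11 rose and 1 fell. Among those that did not pass, ACACA went from 161 to 123 CPM (adjusted p = 0.0723).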
